A study of Caenorhabditis elegans with 4 samples.

How the data were processed

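The samples were Caenorhabditis elegans hermaphrodites of strain OP82 at the L2 stage, grown at 20 °C and crosslinked in 2% formaldehyde, per the labels' protocols. Sonicated chromatin was pulled down with anti-GFP antibodies, and 10% of the supernatant was kept as Input. The labels put 2 libraries in the ChIP group and 2 in the Input group. The analysis used 3 peak lists, 1 for each ChIP replicate and 1 combined; no values of the Input libraries were analysed here.

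Peaks were called with PeakSeq, and the positions are in the WormBase WS220 build, per the file headers. Comment lines in the lists record that positions were lifted over from another build, with 2, 2 and 5 peaks changed in replicate 1, replicate 2 and the combined list. The earlier build, the aligner and the tool used for the liftover are not given in the sources used here. How the combined list was made, whether from pooled reads or otherwise, is likewise not given in the sources used here. The deposited value of each peak is a q-value, the only measurement in the lists, and it was below 0.01 for every peak in all 3. The lists hold no read counts, fold enrichments or summits, so the depth of each library is unknown and no precision from read counts could be given. A q-value depends on depth, so it was used to order peaks within a list, to correlate paired peaks and to describe where the combined q-value lay beside those of the replicates, not as a measure of change between lists.

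The reproducible set (combined-list peaks that met both replicates by at least 1 bp), the tests and the alternatives were chosen before the data were examined, unless stated otherwise. Overlap between replicates was compared with 10000 random placements of one replicate's peaks, with widths kept and each peak on its own chromosome, giving a one-sided permutation p. The reverse count placed replicate 2 peaks against fixed replicate 1 peaks. Placements took no account of mappability or open chromatin and let placed peaks overlap each other. The stronger and weaker 50% of each list by q-value were compared by Fisher's exact test, two-sided. Paired q-values were correlated by Spearman's rho and by Pearson's r on the −log10 scale, with 100000 permutations. Chromosome shares of the reproducible set were compared with the span from the first to the last combined peak of each chromosome by exact binomial tests, two-sided, with Benjamini-Hochberg adjustment over 6 chromosomes. The span stood in for chromosome length because no WS220 sequence was used here. Binomial intervals are exact (Clopper-Pearson, 95%) and cover counting error of peaks alone.

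The regions named are the 10 reproducible peaks with the smallest combined q-value and the 5 widest, a rule fixed for the case that genes could not be placed. The gene table at hand describes WBcel235, another build, so its positions were not used and no gene was assigned to a peak. For the same reason distances to gene starts, binding at gene lists fixed beforehand, sequence motifs and the loci of the transgene were not analysed here. The alternatives tried were other definitions of overlap, stricter lists, a circular shift of the peaks, 25% classes, all combined peaks and leaving out each replicate. A replicate was left out of the rule for reproducible peaks; the combined list itself was not remade.

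Calculations used Python 3.11.15, NumPy 2.4.6 and SciPy 1.17.1, and figures were drawn with matplotlib 3.10.9. The procedures were tested on simulated data. With 0, 100 or 300 shared peaks planted, the overlap count recovered the planted number on average over 20 simulations each, and 3 of 100 pairs of unrelated lists had a permutation p under 0.05. The planted peaks lay apart from each other, and the unrelated lists were made by the same random placement as the test. These runs therefore check the code and do not show how the test behaves when peaks lie in groups in both lists. With 500 simulated peaks, the chromosome test called X in 85.5% of 200 simulations in which the density of peaks on X was 1.5 times that of the other chromosomes. With no effect simulated, the share of exact binomial tests with an unadjusted p under 0.05 was 0.0575. These peaks were drawn independently, so neither value shows how the chromosome test behaves when peaks lie in groups.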

Results

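Chromatin immunoprecipitation and sequencing (ChIP-seq) mapped the DNA bound by CEH-16 in Caenorhabditis elegans hermaphrodites at the L2 larval stage. CEH-16 is a homeodomain protein of the Engrailed family and is known from the seam cells, the lateral epidermal cells of the worm. The animals, of strain OP82, carried a ceh-16 transgene fused to GFP together with an unc-119 rescue marker, and the tagged protein was pulled down with anti-GFP antibodies. The series has 2 immunoprecipitated libraries (ChIP, replicates 1 and 2) and 2 Input libraries of chromatin set aside before the pull-down. Values of the Input libraries were not analysed here. The ChIP libraries each had a peak list, with 1017 peaks covering 499 kb in replicate 1 and 785 peaks covering 392 kb in replicate 2. A combined list held 1848 peaks covering 952 kb. The median peak width was 418 bp, 409 bp and 408 bp in replicate 1, replicate 2 and the combined list. The value of each peak was the authors' q-value, and the read depth behind it is unknown. All positions are in the WS220 build, and no gene was assigned to a peak.

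The first question was which regions were called most strongly in the CEH-16::GFP pull-down. The 10 reproducible regions with the smallest q-values, where reproducible means a combined-list peak that met a peak in both replicates, lay mainly on chromosome IV, which held 6 of them. Chromosomes I, II, III and X held 1 each. The strongest spanned 14032486 to 14034987 on chromosome IV (2502 bp), with a q-value of 1.72e-64 in the combined list, 1.60e-43 in replicate 1 and 1.14e-25 in replicate 2. The second spanned 8610415 to 8626777 on chromosome III and is described with the widest regions. The third spanned 9615196 to 9616018 on chromosome IV (823 bp), with a combined q-value of 3.03e-55, and the fourth spanned 6820927 to 6821615 on chromosome II (689 bp), with a combined q-value of 7.93e-55.

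The other 6 had combined q-values from 5.43e-49 to 1.13e-39. On chromosome IV these were 3232633 to 3234734, 4400731 to 4401400, 1548416 to 1550198 and 13695496 to 13696385. The remaining regions were 8984784 to 8986824 on chromosome I and 6740645 to 6744315 on chromosome X. Among the 10 regions, 8 were within the 20 strongest peaks of both replicates. The exceptions were the chromosome X region, at rank 109 in replicate 2, and the chromosome IV region at 1548416. The latter was at rank 22 in replicate 1 and 101 in replicate 2. Where a region met 2 or more peaks of a replicate, the rank is that of the peak with the largest overlap. The chromosome X region met 2 peaks in replicate 2, and this chromosome IV region met 2 in each replicate. Another of these peaks may therefore rank higher. When peaks had to share at least 50% of the shorter peak, all 10 regions met both replicates. With midpoints required within 200 bp of each other, the 4 narrowest did (670 to 890 bp), and the others, 1783 bp or wider, did not. A fixed midpoint distance is harder to meet for wide peaks.

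The widest called region lay on chromosome III and was 16363 bp long in the combined list, 4.37 times the width of the second widest. It was the strongest peak of both replicates, with q-values of 1.97e-82 in replicate 1 and 2.94e-98 in replicate 2. Replicate 1 had 2 peaks there, from 8616336 to 8623898 and from 8624100 to 8625637, and replicate 2 had a single peak from 8618156 to 8626766. The combined peak began at 8610415, so its part to the left of 8616336 was called in neither replicate. Its combined q-value, 8.70e-59, was larger than that of either replicate, which was the case for 2 of the 555 reproducible regions. The combined q-value was smaller than that of both replicates in 549 of them. For these counts, the q-value in a replicate was that of the peak with the largest overlap. The depths behind the 3 lists are unknown. The strain carries added copies of ceh-16 and unc-119, whose loci were not placed in WS220 here, so whether this region holds transgene DNA was not determined. The next widest regions were 10541924 to 10545666 on chromosome II (3743 bp), 6740645 to 6744315 on chromosome X (3671 bp), 6226710 to 6230008 on chromosome V (3299 bp) and 9059803 to 9062614 on chromosome II (2812 bp).

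**Figure D1:**
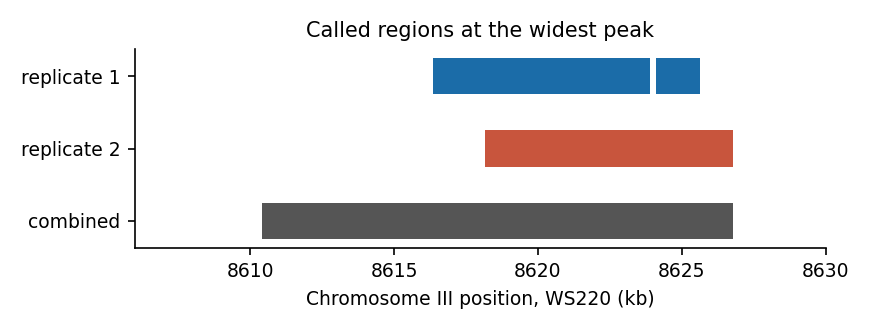
Called regions at the widest peak, drawn against the chromosome III position in kb (WS220), with a row each for replicate 1, replicate 2 and the combined list. Bars run from the start to the end of each peak; the combined peak is 16363 bp long and begins to the left of both replicates' peaks.

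The reproducible regions were spread unevenly over the chromosomes, with most on X and fewest on I. Chromosome X held 150 of the 555 regions, or 27% (95% exact binomial interval 23.4 to 30.9%), against 17.4% of the chromosome span. Chromosome I held 39, or 7.03% (5.04 to 9.48%), against 15%. This came to 8.68 regions per Mb on X and 2.62 on I. Exact binomial tests against the span, two-sided and adjusted by Benjamini-Hochberg over the 6 chromosomes, gave an adjusted p of 5.34e-08 for both. Chromosome II held more than its span share (105 regions, 18.9% against 15.4%) and chromosome V fewer (94 regions, 16.9% against 21%), each at an adjusted p of 0.0377 in the same exact test. Chromosomes III (62 regions, 11.2% against 13.8%, adjusted p = 0.101) and IV (105 regions, 18.9% against 17.4%, adjusted p = 0.341) did not pass the exact test. All these tests count neighbouring regions as independent, which they may not be. A count of groups of close regions was made for X alone, so the shares on I, II and V were not checked for this. In the 50% of regions with the smallest q-values, the shares on I (10.5%, adjusted p = 0.0703) and II (19.5%, adjusted p = 0.0994) no longer passed the exact test. Chromosome V did not pass the exact test when replicate 1 was left out of the rule for reproducible regions, with the combined list unchanged (18.3%, adjusted p = 0.0824).

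**Figure D2:**
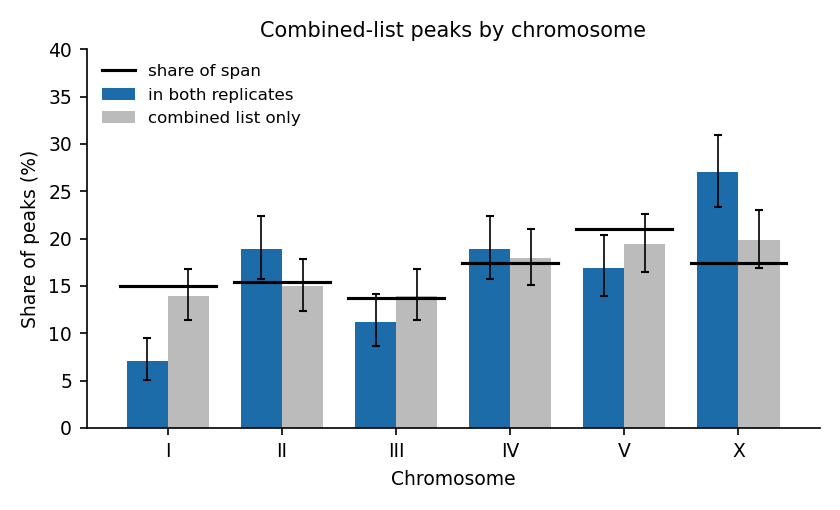
Share of combined-list peaks on each chromosome, in percent, for peaks met in both replicates (blue) and peaks of the combined list alone (grey), with 95% exact binomial intervals. The black line is each chromosome's share of the span; on X the blue bar stands at 27% and the line at 17.4%.

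The next question was whether both immunoprecipitations called the same regions. Of the 1017 peaks of replicate 1, 567 met a replicate 2 peak by at least 1 bp, which is 55.8% (95% exact binomial interval 52.6 to 58.8%). Of the 785 peaks of replicate 2, 568 met a replicate 1 peak, which is 72.4% (69.1 to 75.5%). Random placement of the replicate 1 peaks on their own chromosomes gave a mean of 8.53 and at most 22 in 10000 placements. The one-sided permutation p was 0.0001 in both directions, the smallest these placements can give. Peaks are not independent replicates, and this p covers placement alone. The labels do not say whether the replicates came from separate cultures, so their spread may be technical.

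Sharing was most frequent among the strongest peaks. In the strongest 10% of each list, 98 of 102 replicate 1 peaks (96.1%) and 79 of 79 replicate 2 peaks were shared, against 22.8% and 47.4% in the weakest 10%. In the stronger 50% of replicate 1, 76.2% of peaks were shared, against 35.4% in the weaker 50%, a difference of 40.8 percentage points (Fisher's exact test, two-sided, p = 3.49e-40). In replicate 2 the shares were 89% and 55.7%, a difference of 33.3 percentage points (Fisher's exact test, two-sided, p = 1.87e-26). Both tests count peaks as independent replicates, which they are not. Comparing the strongest 25% with the weakest 25% gave differences of 63.8 and 49.0 percentage points.

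**Figure D3:**
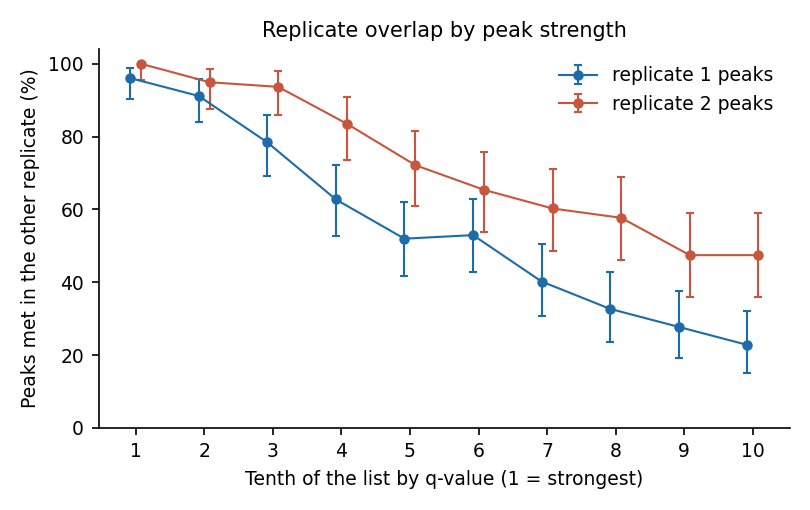
Percentage of peaks met in the other replicate, by position in the list ordered by q-value (1 is the strongest 10% of peaks), for replicate 1 and replicate 2, with 95% exact binomial intervals. The share falls from 96.1% to 22.8% in replicate 1 and from 100% to 47.4% in replicate 2.

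Among peaks called in both replicates, those that were stronger in one replicate tended to be stronger in the other. Over 558 one-to-one pairs of overlapping peaks, Spearman's rho of the q-values was 0.562 and Pearson's r on the −log10 scale was 0.798. Both had a two-sided permutation p of 1e-05, the smallest that 100000 permutations can give. These are correlations across peaks, which are not independent replicates. Pearson's r rested in part on the strongest pairs: without the strongest 5%, 529 pairs gave an r of 0.408 and a rho of 0.492.

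**Figure D4:**
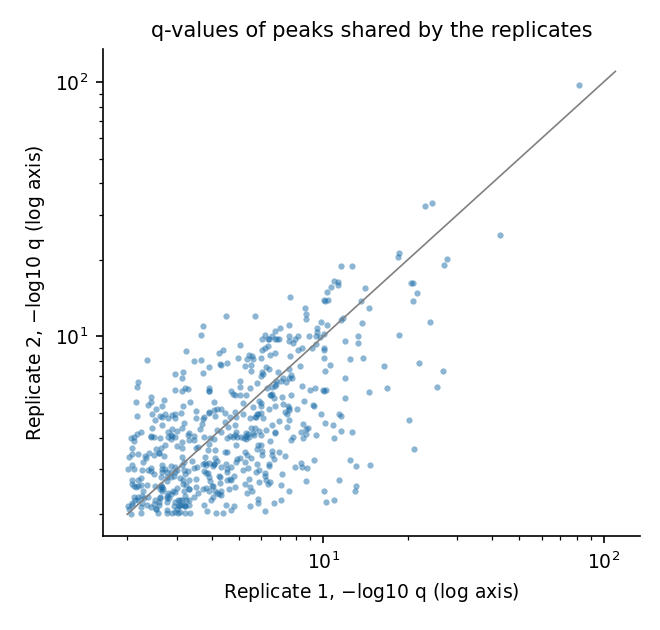
q-values of the 558 pairs of peaks shared by the replicates, as −log10 q on log axes, with replicate 1 on the x axis and replicate 2 on the y axis. Each point is a pair and the line marks equal values; the pair at the upper right is the chromosome III region.

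The combined list was longer than either replicate's list and held regions that neither replicate had called. Of its 1848 peaks, 555 (30.0%, 95% exact binomial interval 27.9 to 32.2%) met a peak in both replicates, 403 (21.8%) in replicate 1 only, 209 (11.3%) in replicate 2 only and 681 (36.9%) in neither. The peaks met in both were stronger and wider, with a median q-value of 4.18e-10 and a median width of 550 bp, against 0.00311 and 330 bp for those met in neither. These medians were not tested, since the classes themselves rest on the q-value threshold of the replicate lists. With each list cut to its 200 strongest peaks, 120 combined peaks met both cut replicate lists and 12 met neither of them. Those 12 may still meet weaker replicate peaks. Against the whole replicate lists, 0 of the 681 combined peaks met in neither reached the median q-value of those met in both.

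In the other direction, the combined list met 977 of the replicate 1 peaks (96.1%) and 781 of the replicate 2 peaks (99.5%). It left out 40 peaks of replicate 1 (3.93%) and 4 of replicate 2 (0.510%). The peaks left out had median q-values of 0.00625 in replicate 1 and 0.00722 in replicate 2.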

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

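All alternatives reported here were chosen before the data were examined. Over 17 results and 60 alternatives, 44 values kept their direction and side of the threshold or stayed within the set margin, 13 moved and 3 fell below the threshold, and none reversed. Stricter lists shortened the counts by construction. In the stronger 50% of each list, 280 replicate 1 and 281 replicate 2 peaks were shared (55.1% and 71.7%), and combined peaks met both replicates in 276 cases, replicate 1 only in 202, replicate 2 only in 109 and neither in 337. Among the 200 strongest peaks of each list, 125 were shared in either direction (62.5%), and the combined classes held 120, 36, 32 and 12 peaks. In both stricter settings the replicate lists were shortened too, so a combined peak that met neither could still meet a weaker replicate peak. Under a circular shift, the highest placements gave 113 and 110 shared peaks, below the 567 and 568 observed. The shift changes the placements alone, so these observed counts are among the 44 values by construction. With midpoints within 200 bp, 512 peaks were shared in either direction. Of the 10 strongest regions, the 4 narrowest still met both replicates under this rule, which is harder for wide peaks to meet. The chromosome I and II shares no longer passed the exact test in the stronger 50% of reproducible peaks (10.5% and 19.5%), where 277 peaks were tested in place of 555. The chromosome V share ranged from 17.1% to 18.3% with a replicate left out of the overlap rule (the combined list was not remade) and did not pass without replicate 1; the cause was not tested. Leaving out a replicate was not possible for comparisons between the replicates. No paired analysis was possible because values of the Input libraries were not analysed here. The alternatives for gene starts, gene lists and motifs were not run, since no WS220 annotation or sequence was used here. Unknown depth limits any comparison of list length between the replicates.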

Other observations

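Of the tests in this part, those of the central parts of chromosomes, of density over megabases and of neighbours at 5 to 10 kb were set before their results were seen. The stronger 50% of regions was an alternative set before the data were examined, used as a test of an explanation only afterwards; all the other tests were chosen afterwards. Called regions often lay close together. Joining combined-list peaks up to 5 kb apart gave 1316 groups, and 851 peaks (46.0%) were in groups of at least 2. There were 19 groups of 5 or more. The largest held 11 peaks, from 6820927 to 6838630 on chromosome II, and began with the fourth strongest reproducible region. Groups of 9 peaks lay at 7799622 to 7819661 on chromosome II and at 9607844 to 9620016 on chromosome IV. The densest megabase was 11 to 12 Mb of chromosome II with 50 peaks, against a median of 18. Next came 2 to 3 Mb (40 peaks) and 13 to 14 Mb (38 peaks) of chromosome X.

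Chromosome IV held 6 of the 10 strongest reproducible regions (60%) and 18.9% of all of them. Its share was 35% in the 20 strongest, 34% in the 50 strongest and 24% in the 100 strongest. None passed Fisher's exact test after Benjamini-Hochberg adjustment over the 24 tests of 6 chromosomes and 4 list lengths, with adjusted p from 0.0886 to 0.766. Adjusted over the 6 chromosomes of each list length alone, the 10 strongest (adjusted p = 0.0263) and the 50 strongest (0.0443) passed the exact test, and the 20 strongest (0.467) and the 100 strongest (0.694) did not.

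The grouping of peaks was weighed against a caller that splits broad regions and against density that varies over megabases. Density over megabases did not account for it: 532 neighbours lay within 5 kb, above the highest of 10000 placements that kept each peak in its own 1 Mb window (262). For split regions, the count set beforehand went with the explanation, with 140 neighbours at 5 to 10 kb against a mean of 153 and a 95th percentile of 172, but that count also falls when many gaps are shorter. As a share of the gaps over 5 kb, examined after that result was seen, it was 10.7%. This was above the 95th percentile of 10.4% in placements over the chromosome (permutation p = 0.02). It was below that of 11.1% within 1 Mb windows (permutation p = 0.1). Of the gaps over 2 kb, 12.9% were 2 to 5 kb long. That was above the highest placement over the chromosome (7.67%) and the highest within 1 Mb windows (8.35%). The excess at 2 to 5 kb is part of the grouping itself and decides nothing, so splitting may account for the grouping and stays open, and no biological explanation was tested.

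The excess on X was weighed against 3 technical explanations. Joining reproducible peaks up to 5 kb apart gave 444 groups, of which 126 (28.4%, 95% exact binomial interval 24.2 to 32.8%) lay on X. With a span share of 17.4%, this argues against a few dense groups of peaks up to 5 kb apart. It does not address stretches of X that are dense over megabases, which were not tested. In the central 50% of each chromosome X held 24.2% of reproducible peaks (19.7 to 29.1%), against 31.4% in the outer parts. The central share argues against sparse calls on the outer autosomes as the whole cause, but the larger outer share leaves a partial contribution open. Calls near the threshold were argued against as the whole cause, since X held 24.9% (19.9 to 30.4%) of the stronger 50%, but its share was 22% in the 100 strongest and 16% in the 50 strongest (adjusted p = 0.901 and 0.467 against the other reproducible regions in Fisher's exact test over the same 24 tests), so whether the strongest regions share the excess stays open. X held 27% of peaks met in both replicates and 19.8% of those met in neither (Fisher's exact test, adjusted p = 0.0104). This contrast was not particular to X. Chromosome I differed in the other direction, with 7.03% and 13.95% (Fisher's exact test, adjusted p = 0.000604). No other chromosome passed this test. Mappability and base composition stay open and untested, and no biological explanation was tested.

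The chromosome III region stood apart by its width. The outer edges of the replicates' peaks differed by 1129 and 1820 bp, above the 95th percentile of 947 bp among 27 other wide peaks, but those peaks are all narrower, so this does not decide whether a copied segment was called from end to end. As for joining of neighbouring peaks, 0 of 29 other combined peaks that joined 2 or more replicate peaks had a q-value larger than in both replicates. Those peaks are all narrower too, so this does not decide whether joining enlarged the combined q-value of so wide a region. Extra copies of transgene DNA could widen a region and stay open, since ceh-16 is a chromosome III gene and its position in WS220 was not used here. Binding itself stays open too, and no biological explanation was tested.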
